A study of Notamacropus eugenii and Pogona vitticeps with 4 samples.

How the data were processed

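Whole testes of the tammar wallaby and the bearded dragon were dissociated and profiled by 10x single-cell RNA-seq. Reads were 50 bp paired, with a target of 5000 to 6000 cells per library. The counts are UMIs per gene and cell barcode that the authors made with Cell Ranger 6.1.2, per the file headers, and Seurat 4.3 is named in the submitters' processing notes. The genome builds and annotations are not given in the sources used here. Each species came as 1 deposited matrix, and 0 of its columns lacked a species. The labels list 2 libraries per species, but the barcodes carry no library number. Each species was therefore treated as 1 pooled sample, with no test and no count of changed genes. The Hi-C and sorted cells that the study design mentions were not used here.

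The wallaby matrix had 33227 features, 19509 of them without a gene symbol, and these held 35.3% of UMIs. The dragon matrix had 17235 features, 754 without a symbol, with 2.90% of UMIs. Barcodes held 500 to 104139 UMIs in the wallaby and 500 to 88341 in the dragon, so a lower limit had been set on the deposited barcodes. Barcodes with fewer than 200 genes were removed (0 in the wallaby, 40 in the dragon). Doublets were scored against 2 simulated doublets per cell over 40 neighbours. The limit was the quantile of the score that leaves 6% of cells, and cells tied with it were kept, which removed 209 wallaby barcodes (5.28%) and 204 dragon barcodes (5.33%). The kept cells held 14934507 and 13586651 UMIs, with medians of 1878 and 1971 per cell. In the summed classes, 3 UMIs correspond to 18.2 CPM in wallaby spermatogonium-like cells and to 1.79, 2.27 and 0.729 CPM in spermatocyte-like, round and elongating spermatid-like cells. In the dragon they correspond to 1.60, 0.653, 1.18 and 1.28 CPM.

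Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen by dispersion in 20 bins of mean. Members of the preset lists and ribosomal protein genes were kept out of the variable genes. Values were clipped at 10, reduced to 30 principal components and clustered by the Leiden method at resolution 1 on 15 neighbours, which gave 25 clusters per species. Clusters were named from preset markers of 10 cell classes. A name needed at least 3 supporting markers (2-fold over the level in all cells, at least 5 UMIs), a score of at least 0.4 and a lead of 0.2 over the next class. The cluster's 50 leading genes also had to hold no larger number of another class's markers. Round and elongating spermatid markers were not counted against each other. Clusters with very low UMIs per cell stayed unnamed unless a marker of their class was among the 10 leading genes. These limits were set after the data had been seen. The wallaby spermatogonium-like cluster was named from DMRT1, ELAVL2, ETV5, PIWIL4, MORC1, ID4, KIT and GFRA1. It scored 2.065 for spermatogonial and 0.954 for spermatocyte markers, and the latter exceeds the 0.801 of spermatocyte-like cluster 7. Markers and variable genes were kept out of the genes named for the largest and smallest ratios, because they defined the classes. They did enter the medians over all genes or features, the random lists and the comparison of shared genes.

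Counts were summed over the cells of a class and scaled to the class total. Log2 ratios had 1 UMI added to each count before scaling. A gene was compared when it had a symbol found once and at least 50 UMIs over the 2 stages. All features with that count entered the all-feature median. A fold against a class with a count of 0 is a lower bound against 3 counts over the class, written as at least that fold. Other folds are ratios of raw counts with exact 95% intervals, and cell shares have exact binomial intervals. The named genes were those with the 8 largest and 8 smallest ratios per species and stage pair, the 2 largest and 2 smallest of each preset list, and up to 4 each way of the X lists. After the data had been seen, genes among the 10 leading genes of a cluster were left out of these results. A few other genes that the rule names are not reported. Genes of multi-copy families, such as the H2B histones, could not be told apart from their copies.

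The 15 preset lists cover somatic cohesin, meiotic cohesin, condensin and SMC5/6, insulator proteins, the nuclear envelope, recombination, damage signalling, Polycomb, heterochromatin, histone exchange, replication, the axoneme, the piRNA pathway, glycolysis and spermatid regulators. The heterochromatin list also holds DNA methylation genes and the histone methyltransferases SETD1B and SETD2, which are not heterochromatin genes. Another 2 lists hold orthologues of human X genes of the long and the short arm. Each list has the median log2 ratio of its measured members, the number that differ at least 2-fold by size alone, and the percentile of the median among 10000 random lists matched on mean expression in 20 bins. A reference annotation of a wallaby assembly was used for names and for X or autosome membership, and not for positions. Counts under 3 set to 3 without the added UMI moved no list median by over 0.25.

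The comparisons, lists, markers and rule for named genes were chosen before the data were examined. Alternatives chosen then were clustering resolutions of 0.5 and 2, doublets kept, cells with at least 1000 UMIs, gene minimums of 10 and 200 UMIs, the mean of per-cell proportions, cells thinned to 500 UMIs, median-of-ratios size factors, and list members allowed among the variable genes. For the X lists they also included chromosome from the reference and all other genes as the comparison. The size factors were computed by the DESeq2 formula, and the package was not run. Shared genes were matched by symbol between species.

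The ratios were tested on simulated data, in which 200 genes were changed 4-fold. The simulated counts were Poisson draws around the pooled profile of the 2 classes at their UMI totals. They held no variation between cells and no error in class naming, so they cover counting error only. In the wallaby 97% of raised and 100% of lowered genes were recovered at 2-fold between spermatocyte-like and spermatogonium-like cells, and 3.18% of unchanged genes went beyond 2-fold. Between round spermatid-like and spermatocyte-like cells these values were 100%, 97.6% and 0.14%. In the dragon 99% or more were recovered in both steps, with 0.14% and 0.18% of unchanged genes beyond 2-fold. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used on a single thread.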

Results

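Whole-testis suspensions of the tammar wallaby (Notamacropus eugenii), a marsupial, and the central bearded dragon (Pogona vitticeps), an agamid lizard, were profiled by droplet single-cell RNA-seq. The series is concerned with genome folding in spermatogonia, primary spermatocytes and round spermatids, and the single-cell data give the expression of each stage. The labels list 2 libraries per species. Cells could not be assigned to a library, so each species was 1 pooled sample and no difference had a replicate check. The wallaby data held 17923395 unique molecular identifiers (UMIs) in 3955 cell barcodes, with a median of 2044 UMIs and 1125 genes per barcode. The dragon data held 16187021 UMIs in 3864 barcodes, with medians of 2053 UMIs and 1138.5 genes. The smallest barcode in either species had 500 UMIs. After removal of barcodes with few genes and of predicted doublets, 3746 wallaby and 3620 dragon cells remained from the 2 libraries of each species. The protocol aimed at 5000 to 6000 recovered cells for each library. All intervals given are 95% intervals for counting error only.

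Cells of the 4 named germ cell stages made up 40.3% of the wallaby cells (interval 38.7 to 41.9%, 1509 cells) and 73.5% of the dragon cells (72.0 to 74.9%, 2659 cells). Somatic classes made up 41.1% and 6.38%. In the wallaby, peritubular or stromal-like cells, which surround and support the seminiferous tubules, were the most abundant class at 27.3% (25.8 to 28.7%), whereas in the dragon they were 0.97% (35 cells). Sertoli-like cells, the nurse cells of the tubule, were 3.47% in the wallaby and 4.50% in the dragon. An unnamed wallaby cluster of 257 cells (cluster 5, 6.86%) scored highest for Sertoli markers, at 1.03, with spermatocyte markers at 0.96. The wallaby Sertoli share thus depended on the limits for naming. Leydig-like cells (3.36%), which make testosterone, and leukocyte-like cells (2.30%) were named in the wallaby and not in the dragon. An unnamed dragon cluster of 19 cells (cluster 25, 0.52%) had the leukocyte marker CD74 among its leading genes, so leukocytes were not shown to be absent there. Endothelial-like cells were 4.70% and 0.91%. These shares stand side by side without a test, because species, dissociation and gene annotation differ together.

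Spermatogonium-like cells, the diploid cells that divide by mitosis before meiosis, were 0.88% of wallaby cells (0.61 to 1.23%, 33 cells, cluster 24) and 10.8% of dragon cells (9.78 to 11.8%, 390 cells, clusters 7 and 8). Spermatocyte-like cells, in meiotic prophase, were 21.4% in the wallaby (803 cells, clusters 1, 7 and 13) and 25.3% in the dragon (914 cells, clusters 3, 5, 6, 14 and 17). Round spermatid-like cells, the first haploid stage, were 9.34% (350 cells, clusters 2 and 18) and 29.9% (1083 cells, clusters 1, 2, 10, 11, 15 and 18). Elongating spermatid-like cells were 8.62% (323 cells, clusters 3 and 20) and 7.51% (272 cells, clusters 9 and 20). Another 18.6% of wallaby cells and 20.2% of dragon cells stayed unnamed, some with germ cell markers and some with somatic markers. One unnamed wallaby cluster of 172 cells (cluster 10, 4.59% of cells) carried spermatocyte markers but had more spermatogonial markers among its leading genes. Counting it as spermatogonium-like raised that share to 5.47%, so the wallaby spermatogonial share depended on this choice. Cluster 24 itself also scored 0.954 for spermatocyte markers, against 2.065 for spermatogonial markers, so the class may not be purely premeiotic.

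**Figure D1:**
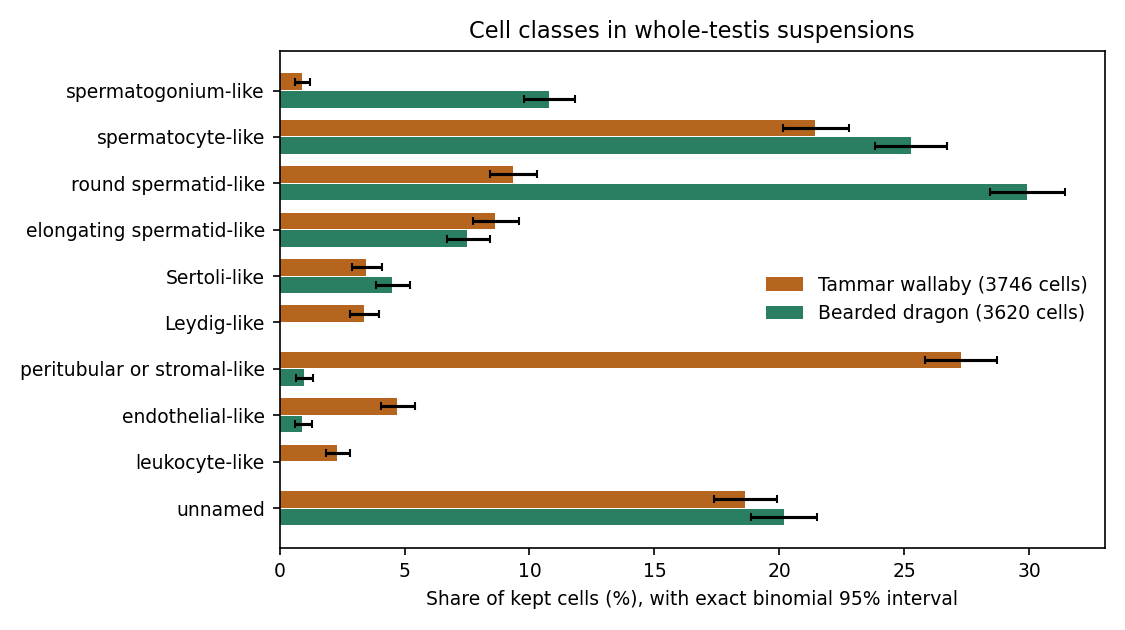
Share of kept cells (%, horizontal axis) in each cell class (vertical axis) for the tammar wallaby (3746 cells) and the bearded dragon (3620 cells), with bars for shares and whiskers for exact binomial 95% intervals. Peritubular or stromal-like cells were 27.3% in the wallaby and 0.97% in the dragon, and round spermatid-like cells 9.34% and 29.9%.

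Among germ cell stages, elongating spermatid-like cells held the most UMIs, with a median of 4837 UMIs in the wallaby and 6989 in the dragon, against 2096 and 1874 in round spermatid-like cells. At equal depth they had the fewest genes of the 4 stages. Thinned to 500 UMIs, they showed a median of 250 genes per cell in the wallaby and 340 in the dragon. Round spermatid-like cells thinned alike showed 393.5 and 404 genes, spermatocyte-like cells 399 and 424, and spermatogonium-like cells 452 and 420. Without thinning the medians were 2110, 765, 1180 and 1126 genes from spermatogonium-like to elongating cells in the wallaby and 1229.5, 1282.5, 1084 and 1608.5 in the dragon. Thinning left out 0 cells.

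The comparison of spermatocytes with spermatogonia asks which genes change as cells enter meiosis. In the wallaby the clearest difference was in genes of the axoneme, the microtubule core of the sperm tail. Of 26 measured axoneme and cilium genes, 22 were at least 2-fold higher in spermatocyte-like than in spermatogonium-like cells and 0 were at least 2-fold lower. Their median log2 ratio was 2.94, against 0.07 over 4905 named genes, and lay at percentile 100 of 10000 matched random lists. DNAH1, an axonemal dynein heavy chain, was 46.4-fold higher (12.8 to 384), at 562 against 12.1 CPM (UMIs of a gene scaled to the total of the class). CFAP43, a flagellar protein, was at 424 against 6.05 CPM, a ratio of 70.1 (12.5 to 2772) on 1 UMI, with a log2 ratio of 1.27 among cells with at least 1000 UMIs. SPAG16 and RSPH4A, other axoneme genes, went the other way, with log2 ratios of -0.62 and -0.43, but were above 0 in some settings (up to 0.13 and 0.31).

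Outside the preset lists, the genes with the largest wallaby ratios were of mixed function, with cilium genes among them. MORN1 was at least 27.4-fold higher and CFAP74, a component of the axoneme, at least 19.9-fold higher in spermatocyte-like cells, since neither had a UMI in spermatogonium-like cells. SAP18, a subunit of a histone deacetylase complex, was at least 16.7-fold higher, and NUPL2, a nucleoporin, at least 15.1-fold. MRPS34, a mitochondrial ribosomal protein, was at least 12.0-fold higher. CCDC60 and FBXW10 had 1 UMI each in spermatogonium-like cells, with ratios of 70.3 (12.6 to 2780) and 68.9 (12.3 to 2725). These ratios depended on the setting. Their lowest log2 values were 2.56 for MORN1, 2.14 for CFAP74 and 1.81 for FBXW10 in thinned cells, with CCDC60 between the last 2, and 2.88 for NUPL2, 1.32 for MRPS34 and 0.16 for SAP18 with doublets kept. In somatic cells MORN1 was at 8.67 CPM, against 498 CPM in spermatocyte-like cells.

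Genes with the lowest wallaby ratios were of mixed function too. CDK6, a kinase of the entry into S phase, was 131-fold lower in spermatocyte-like cells (81.2 to 225), at 10.8 against 1410 CPM. TIAM2, an activator of the GTPase RAC, was 422-fold lower (141 to 2075), with 3 UMIs left in spermatocyte-like cells. DLG5, a scaffold of cell junctions, was 248-fold lower (65.1 to 2107). CADPS2, ATP8A1, ZNF521, SPATS2L and PQLC1 completed the 8 lowest, with log2 ratios from -7.22 to -6.46.

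Of 13 wallaby spermatid regulators, 8 were at least 2-fold higher in spermatocyte-like cells and 3 lower, with a median of 1.23 that lay inside the central 95% of random lists (percentile 97.3). MEIG1, needed for spermiogenesis, stood at 275 against 6.05 CPM, a ratio of 45.4 (8.11 to 1797). ELAVL4, an RNA-binding protein, was lower, with a log2 ratio of -4.41. BRDT, the testis bromodomain protein that reads acetylated histones, was 9.69-fold higher (7.88 to 12.1), at 5282 against 545 CPM and 43.2 CPM in somatic cells. The histone exchange list as a whole had a median of 0.07, with 5 of 15 genes higher and 4 lower. ENO1, a glycolytic enolase, was 14.6-fold higher (7.07 to 36.5), and 3 of 5 glycolysis genes were at least 2-fold higher (median 1.02).

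Genes of chromosome architecture were mostly lower or little different in the wallaby. STAG1, a cohesin subunit, had a log2 ratio of -1.69 and 9 of 10 somatic cohesin genes differed less than 2-fold (median -0.48). The meiotic cohesin genes SMC1B and STAG3 had log2 ratios of 0.82 and 0.13, with a median of 0.48 over those 2. Of 15 condensin and SMC5/6 genes, 6 were lower and 2 higher (median -0.79). TOP2B, a DNA topoisomerase, was at -2.87 and SMCHD1, a chromatin protein of the inactive X, at -1.81. The 5 measured insulator genes had a median of -0.90, with ADNP at -1.62. In the nuclear envelope list 4 of 10 were lower and 4 higher (median -0.55), and SYNE1, which links the nucleus to the cytoskeleton, was at -2.99.

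Meiotic and chromatin lists were mixed in the wallaby. Of 17 recombination genes, 6 were lower and 2 higher (median -0.80), with ANKRD31, needed for double-strand breaks on the sex chromosomes, 12.2-fold lower (9.24 to 16.0) and HFM1, a crossover helicase, at -2.86. Damage signalling genes had a median of 0.73, with 4 of 10 higher and 2 lower, but of -0.36 with doublets kept. MDC1, which spreads the damage mark along the silenced X, was 19.3-fold higher (5.31 to 160), and BRCA1 had a log2 ratio of -1.55. Polycomb genes had a median of -0.02, with PHC1 at 2.70 and RNF2 at -2.11. The heterochromatin and DNA methylation list had a median of 0.07, with SETD1B at 2.85 and HELLS, a remodeller of DNA methylation, at -1.84. The piRNA genes, which silence transposons, had a median of 0.27, with TDRD12 at 1.38 and ASZ1 at -1.90. The 6 replication genes had a median of -0.34, with MCM3 at -1.66.

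Of 6648 wallaby features, 55.2% were higher in spermatocyte-like cells. Median-of-ratios size factors moved the median feature of 0.27 by 0.75 and that share to 69.2%, while 5 other settings put the median below 0. Under those factors the medians of somatic cohesin (0.26), nuclear envelope (0.20), replication (0.40) and Polycomb (0.73) were above 0, and counting cluster 10 as spermatogonium-like kept the sign of 80 of 86 named genes but moved 45 by over 1.5-fold. With thinned cells 4 of 8 list medians kept their sign. Condensin and SMC5/6 genes reached 0.39 at a minimum of 200 UMIs, and the heterochromatin and histone exchange medians, near 0, were as low as -0.67 and -0.65.

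In the dragon the same comparison rested on 390 spermatogonium-like cells. Axoneme genes stood apart here too: 25 of 26 were at least 2-fold higher in spermatocyte-like cells and 0 lower, with a median log2 ratio of 2.67 (percentile 100) against -0.24 over 9031 named genes. CFAP43 was 31.9-fold higher (21.4 to 50.0), at 409 against 12.8 CPM, and CFAP69 21.3-fold (12.8 to 38.3). DNA replication genes were lower as a group, with 14 of 22 at least 2-fold lower and 2 higher (median -1.31, percentile 0.06). MCM7, a subunit of the replicative helicase, was 7.05-fold lower (5.47 to 9.17), and GMNN, an inhibitor of replication licensing, was 5.93-fold higher (4.19 to 8.66).

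Insulator genes were also lower as a group in dragon spermatocyte-like cells, with 5 of 10 at least 2-fold lower and 1 higher (median -0.98, percentile 2.27). CTCFL, the germline paralogue of CTCF, was 12.3-fold lower (10.1 to 14.97), at 27.2 against 333 CPM. LDB1, a factor of looping between enhancers and promoters, had a log2 ratio of -2.69, and MAZ was higher at 1.69. The percentile of the insulator list was inside the central 95% in 4 of 13 other settings, up to 9.24 with cells thinned to 500 UMIs. That of the replication list was inside it with thinned cells, at 13.4.

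Among other dragon genes, PEX11A, a peroxisome division factor, stood at 160 against 0.533 CPM, a ratio of 300.4 (53.8 to 11880) on 1 UMI in spermatogonium-like cells. CCDC42, needed for sperm tail formation, had a ratio of 204 (56.3 to 1687), and DNAI4, an axonemal dynein chain, of 114 (44.2 to 418). RFX6, a transcription factor, was at least 31.0-fold higher. OTUD7A, PPIL6 and ADAM2 were higher as well, ADAM2, a sperm surface protein, by 60.0-fold (32.6 to 126), with 17.0 CPM in somatic cells. HMGA1, a chromatin protein of dividing cells, was at least 67.0-fold lower. MCAM, an adhesion molecule, was 89.0-fold lower (40.3 to 245). SLC2A1, a glucose transporter, was 129.9-fold lower (22.3 to 5225), with 1 UMI left. APBA3 and TMEM120B had log2 ratios of -6.29 and -6.10.

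The dragon's glycolysis and spermatid genes held both directions. PKM, pyruvate kinase, was 28.1-fold higher (22.1 to 36.4), at 1005 CPM against 308 CPM in somatic cells, and PFKP 16.9-fold (13.2 to 21.8). ENO1 was 9.01-fold lower (7.61 to 10.7), the opposite of the wallaby, and the list had 3 of 11 genes higher and 4 lower (median -0.84). YBX2, which stores mRNA in germ cells, was 27.8-fold higher (23.6 to 32.9), and MEIG1 15.7-fold (10.8 to 23.7). Of 12 spermatid regulators 5 were higher and 2 lower (median 0.77). BRDT was 12.5-fold higher (9.43 to 17.0), while 1 of 19 histone exchange genes was higher and 4 lower (median -0.41).

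Meiotic genes were split in the dragon. TEX11, a crossover factor, was 13.0-fold higher (8.36 to 21.5) and MCM8, a recombination helicase, 6.68-fold (5.10 to 8.92), while its partner MCM9 was 7.47-fold lower (5.58 to 10.1). Recombination genes had 6 of 19 higher and 1 lower (median 0.45). The meiotic cohesin genes SMC1B, STAG3 and REC8 were each lower, with log2 ratios of -0.80, -0.89 and -1.19. NIPBL, the cohesin loader, was higher at 1.10, and the other 11 somatic cohesin genes differed less than 2-fold (median -0.53). Condensin and SMC5/6 genes had a median of 0.23, with SMCHD1 at 1.23 and TOP2A at -1.22. Nuclear envelope genes had a median of 0.36, with TERB2, a telomere tether, at 2.33 and SUN2 at -1.67. Damage signalling genes had a median of -0.45, with CHEK1 at -2.32, and piRNA genes of -0.55, with PNLDC1 at -2.99. Polycomb genes (median -0.24) ranged from CBX2 and BMI1, higher at 4.49 and 3.85, to CBX7 at -4.36. Heterochromatin genes (median -0.48) included SUV39H1, a histone H3 lysine 9 methyltransferase, at 2.42 and DNMT3A, a DNA methyltransferase, at -2.81.

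Of 10800 dragon features, 43.1% were higher in spermatocyte-like cells. Size factors moved the median feature by 0.44 and that share to 56.7%, and turned the medians of Polycomb (0.20) and histone exchange (0.02) above 0. With thinned cells these 2 (0.55 and 0.17) and damage signalling (0.22) were above 0.

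The comparison of round spermatids with spermatocytes covers the exit from meiosis. In the wallaby most named genes were lower in round spermatid-like cells, with a median log2 ratio of -0.88 over 5743 genes. Genes of the heterochromatin and DNA methylation list were lower still, with 5 of 9 at least 2-fold lower and 0 higher (median -2.55, percentile 0.51). SETD1B had a log2 ratio of -4.15 and SUV39H2, a testis histone H3 lysine 9 methyltransferase, of -4.03, while EHMT1 was higher at 0.91. The piRNA genes had 11 of 13 lower and 1 higher (median -2.01, percentile 3.33), with TDRD5 16.1-fold lower (9.06 to 31.6) and GTSF1 higher at 1.36. The percentile of the heterochromatin list was inside the central 95% in 5 of 14 other settings, up to 40.73 with thinned cells.

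Meiotic genes did not move together in the wallaby. MEI4 and MND1, factors of double-strand break formation and strand exchange, were higher in round spermatid-like cells, MND1 7.38-fold (6.25 to 8.76) at 732 CPM. MEI4 had a log2 ratio of 3.23 and 538 CPM, against 124 CPM in somatic cells. BRCA2 and MCMDC2 were lower, at -3.17 and -3.07, and 10 of 18 recombination genes were lower and 5 higher (median -1.19, but 1.98 at a minimum of 200 UMIs). The meiotic cohesin genes split as well. RAD21L1 was higher at 2.67, STAG3 was 3.13-fold higher (2.66 to 3.69) and SMC1B was at -1.06, with a median of 1.64. Of 11 damage signalling genes 9 were lower, with a median of -2.06 that lay inside the central 95% of random lists (percentile 7.29), and with RAD9B and RAD1, of the checkpoint clamp, at -3.58 and -3.51.

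Lists of chromosome structure and division had medians below 0 in wallaby round spermatid-like cells, and all of them lay inside the central 95% of random lists. Somatic cohesin, insulator and nuclear envelope genes lay close to the all-gene median of -0.88. CTCF had a log2 ratio of -1.81, from 28.7 to 7.57 CPM, and 3 of 6 insulator genes were lower (median -0.94). Of 15 condensin and SMC5/6 genes 10 were lower and 0 higher (median -1.33), with NCAPG2 at -2.73. ESPL1, the protease that opens cohesin, was at -3.36, and 5 of 10 somatic cohesin genes were lower (median -0.97). NIPBL was higher at 0.59. MKI67, a mark of dividing cells, was 35.8-fold lower (15.1 to 111), and 6 of 7 replication genes were lower (median -2.29). LEMD2, of the inner nuclear membrane, was at -4.79 and 4 of 10 nuclear envelope genes were lower (median -0.81). Polycomb genes had a median of -0.63, with SUZ12 at -2.05. Histone exchange genes had a median of -1.17, with 8 of 16 lower, and CHD5, which acts in histone removal, was higher at 1.84.

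The genes with the largest wallaby ratios in this step included some ion channel subunits, a group that no preset list covers. KCNAB1, a potassium channel subunit, had a ratio of 139 (47.3 to 679), at 249.8 against 1.79 CPM, and ADAMTSL1 of 117 (39.8 to 573). CACNB3 and CACNG1, calcium channel subunits, were at least 61.2-fold and 28.3-fold higher. CDH23, ERGIC1, F12 and TSPAN11 completed the 8 highest. TOM1, an endosomal sorting protein, was at least 23.9-fold lower and UPP2, a uridine phosphorylase, at least 18.4-fold. PFKM, the muscle phosphofructokinase, was 18.7-fold higher (9.57 to 41.9) and PGAM2 was at 2.75, with 4 of 7 glycolysis genes higher and 2 lower (median 1.35). KLHL10, a spermatid ubiquitin ligase adaptor, was at 2.21, and BOLL, a meiotic RNA-binding protein, was 10.5-fold lower (7.18 to 16.1). Spermatid regulators had 4 of 13 higher and 7 lower (median -1.49). Axoneme genes had a median of -0.38, with CFAP43 4.86-fold higher (4.48 to 5.29) and DNAI2 at -1.95.

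Of 8237 wallaby features 38.7% were higher in round spermatid-like cells, and size factors moved the median feature by 0.47, the share to 46.6% and the axoneme median to 0.08. With a clustering resolution of 2, which moved the round spermatid-like share to 14.9%, 77 of 89 named genes kept their sign and 74 moved by over 1.5-fold. At that resolution NIPBL (-0.50) and EHMT1 (-0.15) were below 0. With thinned cells 5 of 11 list medians kept their sign, and glycolysis was at -1.58, somatic cohesin at 0.20, Polycomb at 0.55 and histone exchange at 0.14. The nuclear envelope median was 0.76 at a minimum of 200 UMIs.

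In the dragon, most meiotic gene groups were lower in round spermatid-like cells. Recombination genes were at least 2-fold lower in 14 of 19 cases and higher in 0 (median -2.24, percentile 0.01), and piRNA genes in 14 of 16 with 1 higher (median -2.76, percentile 0.0). TEX11 was 39.4-fold lower (20.6 to 86.6) and ZCWPW1, a reader of recombination sites, 28.5-fold lower (20.5 to 40.9). MAEL was 40.03-fold lower (21.6 to 83.8) and TDRD1 25.4-fold lower (18.5 to 36.1), while TDRD7 was higher at 2.62. Replication genes (19 of 21 lower, median -2.57, percentile 0.04) and condensin and SMC5/6 genes (10 of 16 lower, median -1.80, percentile 0.17) were also beyond the central 95% of random lists, the latter not at a minimum of 200 UMIs (percentile 2.76). NCAPG2, a condensin subunit, was 156-fold lower (27.7 to 6170) with 1 UMI left, and GMNN was 16.2-fold lower (9.99 to 28.0).

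Heterochromatin genes (12 of 16 lower, median -1.90, percentile 0.55) and damage signalling genes (9 of 13 lower, 2 higher, median -2.29, percentile 1.28) completed the 6 lists beyond that range. SUV39H1 was 26.8-fold lower (13.96 to 58.9) and DNMT1, the maintenance DNA methyltransferase, 9.45-fold lower (5.41 to 18.0). CHEK1 was at least 9.82-fold lower, and ETAA1 and HUS1 were higher at 1.58 and 1.32. With cells thinned to 500 UMIs the damage signalling median was 0.23, so its direction did not hold there.

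Cohesin and insulator genes had medians below 0 too in the dragon, inside the central 95% of random lists, against an all-gene median of -0.82 over 8611 named genes. CTCF had a log2 ratio of -0.91, from 188 to 99.8 CPM, and 7 of 9 insulator genes were lower (median -1.57), with ZNF143 at -3.13. STAG3, SMC1B and REC8 were at -1.13, -1.46 and -2.67, and PDS5A, a cohesin regulator, was the lowest of the somatic cohesin genes at -2.69 (median -1.03). TERB1, which ties telomeres to the nuclear envelope, was 11.9-fold lower (9.58 to 14.9). SYNE1 went the other way, at 570 against 115 CPM (214 CPM in somatic cells), in a list with 10 of 14 genes lower (median -1.43). Polycomb genes had a median of -0.81, with PCGF6 at -2.17, and histone exchange genes of -1.17, with 12 of 19 lower.

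Several genes of sperm structure and energy were higher in dragon round spermatid-like cells, in lists that stayed inside the central 95% of random lists. TEKT3, a tektin of the tail microtubules, was 20.7-fold higher (16.6 to 26.0), and axoneme genes had 6 of 26 higher and 1 lower (median 0.37). ALDOA was 7.43-fold higher (5.61 to 9.97) and PFKM 6.41-fold (4.82 to 8.64), with 5 of 12 glycolysis genes higher and 3 lower (median 0.51). KLHL10 was 11.4-fold higher (8.18 to 16.3) and SOX30, a spermatid transcription factor, at 2.56. DAZL, a germ cell RNA-binding protein, was 8.93-fold lower (6.28 to 13.1), and the spermatid list had a median of -0.19. BTBD16 was 146-fold higher (95.9 to 233), at 698 CPM against 7.70 CPM in somatic cells. FSCN3, a testis actin-bundling protein, had a ratio of 128 (43.3 to 627), and OVOL1, a transcription factor, was at least 33.0-fold higher. CIMAP2, SLFNL1, AKIP1, LRRC37A3 and a gene given only as PODLI_1B020555 completed the 8 highest. CEP57L1, a centrosome protein, was 156-fold lower (27.8 to 6192) and POU2F2 at least 21.5-fold lower.

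Of 10385 dragon features, 33.4% were higher in round spermatid-like cells. Size factors moved the median feature by 0.65, that share to 47.2% and the spermatid list's median to 0.46.

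Marsupial males are XY, and the X is silenced in meiosis in therian mammals. Orthologues of genes on the human X long arm lie on the marsupial X, and those of the short-arm genes chosen for the list on a marsupial autosome. In a wallaby reference annotation 90 of 94 long-arm orthologues lay on X, and 57 of 58 short-arm orthologues on chromosome 5, with the other 4 and 1 not matched. The measure set in advance rested on few X genes, since its minimum count over the 2 stages leaves out genes that are low in both. The long-arm median minus the short-arm median was 0.63 for spermatocyte over spermatogonium, from a median of -0.20 over 5 genes and -0.83 over 30. For round spermatid over spermatogonium it was -0.07, from 4 and 24 genes. Under other settings the first difference ranged from -2.54 to 0.92 and the second from -2.10 to 0.70, so this measure gave no stable direction. In the dragon, a ZW lizard in which these orthologues are held to be autosomal, the differences were -0.02 (77 and 47 genes) and 0.05.

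A measure chosen after seeing how few X genes reached the minimum count was the summed share of list UMIs. In the wallaby the long-arm list took 235.5 UMIs per 100000 in spermatogonium-like cells (213 to 260.1) and 72.7 in spermatocyte-like cells (68.6 to 76.9), a ratio of 0.309 (0.275 to 0.347). The short-arm list went from 721 to 386 per 100000, a ratio of 0.536 (0.503 to 0.570). Round spermatid-like cells held 73.1 long-arm UMIs per 100000 (68.5 to 77.8), 1.01 times the spermatocyte level (0.923 to 1.10). That ratio was 1.10 (1.01 to 1.21) without ribosomal proteins and 1.14 (1.09 to 1.19) over the 273 genes that the reference placed on X. The spermatocyte-like clusters 1, 7 and 13 held 71.2, 100.2 and 34.8 per 100000. Somatic cells held 504 per 100000 and Leydig-like cells 1042. Those 273 genes gave a ratio of 0.393 (0.367 to 0.422) for spermatocyte over spermatogonium. The X ratio was between 0.188 and 0.331 in 9 other settings and 0.518 with size factors, which put the short-arm ratio at 0.899.

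Gene by gene, with no UMI added, 50 of 71 wallaby long-arm genes with at least 50 UMIs over all cells were lower in spermatocyte-like cells, 41 of them at least 2-fold, while 17 had no UMI in spermatogonium-like cells. Of 52 short-arm genes 30 were lower, 19 at least 2-fold, and 9 had no such UMI. That minimum was also chosen after seeing the data. THOC2, an mRNA export factor, was 12.4-fold lower (8.76 to 17.7). TAF1 and MTMR1 were at log2 ratios of -0.45 and -0.20, and both were above 0 under size factors. HMGB3, with no UMI in spermatogonium-like cells, was at least 1.65-fold higher. RPL39, a ribosomal protein, was higher at 2.02 but lower in 5 other settings. Among short-arm genes SHROOM2 was at -5.61 and DMD, dystrophin, at -3.44, while CA5B and EFHC2 were higher at 4.36 and 3.36. In round spermatid over spermatocyte the long-arm median was 0.06 over 14 genes (percentile 98.7, beyond the central 95%), and the short-arm median -0.25 over 37, with ACSL4 at 1.97 and HMGB3 at -4.33. In the dragon the long-arm share went from 982 to 736 per 100000, a ratio of 0.750 (0.737 to 0.764), and the short-arm share from 433 to 516, a ratio of 1.19. The long-arm ratio was 0.629 times the short-arm ratio in the dragon and 0.576 times in the wallaby, or 0.692 and 0.511 times without ribosomal proteins. For spermatocyte-like over somatic cells these quotients were 0.726 and 0.267. Gene by gene, 53 of 89 dragon long-arm genes were lower, 30 at least 2-fold, and 27 of 50 short-arm genes, 14 at least 2-fold.

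**Figure D2:**
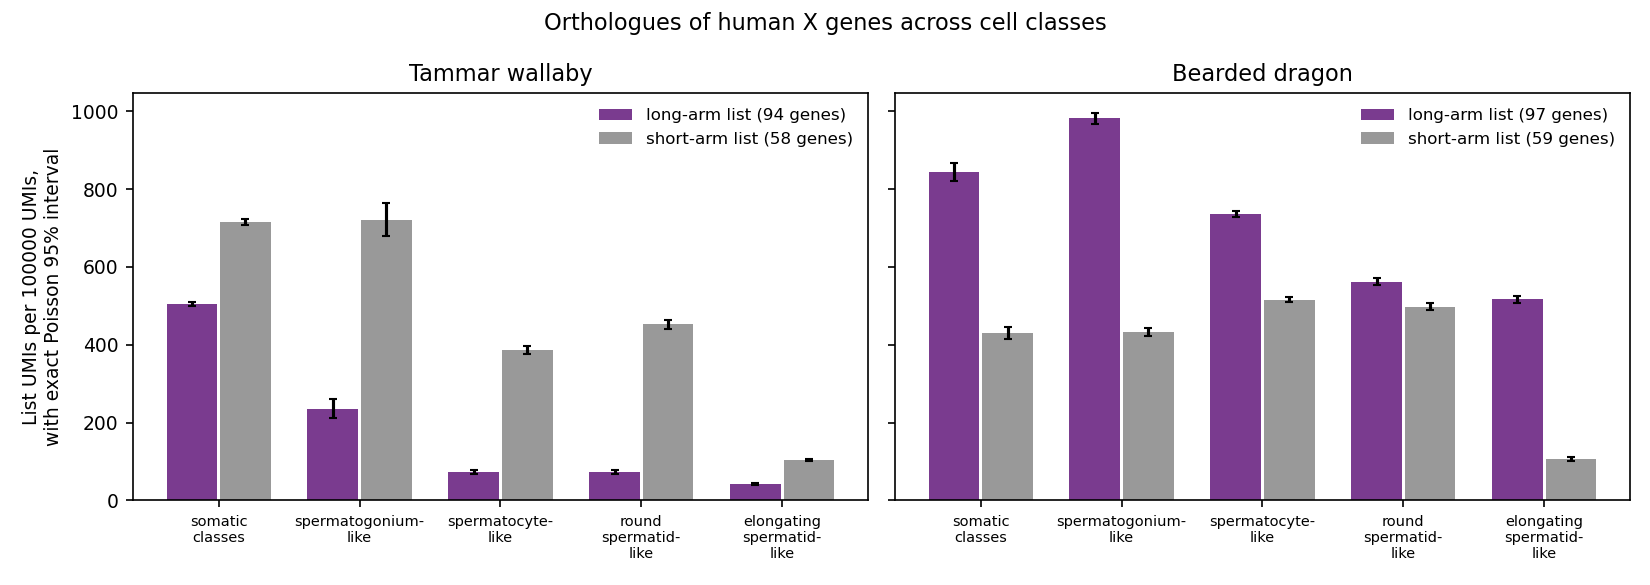
UMIs of the long-arm and short-arm lists of human X orthologues per 100000 UMIs (vertical axis) in somatic and germ cell classes (horizontal axis) of the tammar wallaby and the bearded dragon, with whiskers for exact Poisson 95% intervals. In the wallaby the long-arm bars stand at 504 in somatic cells, 235.5 in spermatogonium-like, 72.7 in spermatocyte-like and 73.1 in round spermatid-like cells.

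Genes with the same symbol in both species show how far stage differences were shared. They include class markers, the same set in both species, and genes used to cluster. Their agreement is therefore not independent of how the classes were named. From spermatogonium-like to spermatocyte-like cells 54.1% of 3538 shared genes had the same sign (52.4 to 55.8%), with a Spearman correlation of 0.14 across genes, which are not independent replicates. Axoneme genes had the same sign in 22 of 23, with medians of 3.01 and 2.65. Spermatid regulators had the same sign in 9 of 9, and nuclear envelope genes in 1 of 8. Preset list members together had the same sign in 99 of 160 (61.9%). From spermatocyte-like to round spermatid-like cells 68.9% of 3840 genes had the same sign (67.4 to 70.3%; Spearman 0.27), and 61.0% lay on the same side of each species' median. In that step the same sign was found for 9 of 10 damage signalling genes, 10 of 12 piRNA genes, 8 of 10 recombination genes, 7 of 8 heterochromatin genes and 6 of 6 insulator genes. Since both species' medians were below 0, fewer lay on the same side of the median, at 8, 9, 7, 5 and 4. Somatic cohesin (3 of 9), nuclear envelope (3 of 8) and Polycomb genes (2 of 7) were the least alike by that measure. Axoneme genes had the same sign in 9 of 23 but lay on the same side of the median in 21. With cells thinned to 500 UMIs the share in the first step was 49.8%, so a shared direction across all genes was not shown there.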

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

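The 4 list differences below were found by a rule applied to all lists, and no explanation of them was tested. They are given because the list median, taken relative to the median over all named genes, lay on opposite sides of 0 in the 2 species, at least 0.5 away from it in each. The differences themselves were not tested, since each species was 1 pooled sample.

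In spermatocyte over spermatogonium, nuclear envelope genes lay at -0.62 in the wallaby and 0.60 in the dragon, a difference of -1.22. SYNE1 was lower in the wallaby (-2.99) and higher in the dragon (1.95). Recombination genes lay at -0.87 and 0.70, a difference of -1.57, though 6 of 10 shared genes had the same sign. Glycolysis genes lay at 0.94 and -0.60, a difference of 1.54, with ENO1 at 3.68 and -3.17. In round spermatid over spermatocyte, spermatid regulators lay at -0.61 and 0.63, a difference of -1.24. On the 9 regulators measured in both species the medians were 0.05 and 0.08, with the same sign in 7, so this difference was not seen on shared genes. The medians on shared genes of the first step were -0.99 and 0.44 for 8 nuclear envelope genes, -0.55 and 0.45 for 10 recombination genes and 1.43 and -0.56 for 4 glycolysis genes. Species, dissociation, annotation and the makeup of the spermatogonium-like class differ together here.

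Wallaby features without a symbol held 35.27% of UMIs, given because they are a signal outside the named genes that the comparisons use. The most abundant of them held 4.90% of UMIs in all cells and 17.1% in elongating spermatid-like cells, against 0.213% in round spermatid-like and 0.127% in somatic cells.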

How the results depend on the processing

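These settings were chosen after seeing the data: the mixed wallaby cluster counted as spermatogonium-like, clusters with a median under 1000 UMIs left out, the gene minimum over all kept cells (also with counts under 3 set to 3), random lists from genes not used to cluster, and the summed X share with or without ribosomal proteins or with size factors. No paired analysis was possible because the barcodes carry no library number, each species was 1 pooled sample and no test was made. The planned edgeR and DESeq2 tests, the replicate block, leaving out 1 replicate and the edgeR filter on low counts were not run for the same reason. Where values moved, the cause was not tested. The 33 wallaby spermatogonium-like cells, with 165196 UMIs, limit the wallaby ratios over spermatogonia, since 3 UMIs there are 18.2 CPM.

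Of 3381 values of 356 single-gene ratios under other settings, 2702 stayed within the counting interval and 69 had the opposite sign, 18 of them in genes that differed at least 2-fold. Of 777 values of 59 list medians, 51 had the opposite sign, 1 of them in a list beyond the central 95% of random lists. Within the interval of the median stayed 751, but that interval measures spread between list members and not counting error. For the shortest lists it runs from the lowest to the highest member, so staying within it says little about stability. The axoneme median of spermatocyte over spermatogonium stayed above 0 in every setting run, from 1.47 to 3.73 in the wallaby and from 2.39 to 3.1 in the dragon.

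Wallaby spermatogonium-like cells were 0.88% and became 5.47% at resolution 0.5, 5.21% with doublets kept, 4.03% among cells with at least 1000 UMIs and 5.47% with the mixed cluster. At least 1000 UMIs moved spermatocyte-like cells to 14.24%, round spermatid-like to 11.78%, elongating to 13.01% and unnamed to 9.25%. Resolution 2 gave 14.9% round, 7.45% elongating and 15.56% unnamed, doublets kept 8.29% round and 14.87% unnamed, resolution 0.5 15.11% unnamed, and the mixed cluster 14.04% unnamed. In the dragon, at least 1000 UMIs gave 6.51% spermatogonium-like, 16.58% spermatocyte-like, 32.13% round, 9.95% elongating and 30.7% unnamed. Resolution 0.5 gave 20.97% spermatocyte-like, 23.7% round and 30.66% unnamed, resolution 2 gave 23.67%, 27.87%, 5.03% elongating and 26.27% unnamed, and doublets kept gave 21.81% spermatocyte-like and 23.38% unnamed.

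The all-feature median of wallaby spermatocyte over spermatogonium was 0.27. It was -0.16 at resolution 0.5, -0.27 with doublets kept, -0.13 at 1000 UMIs per cell, -0.17 at 10 UMIs per gene, 0.87 at 200, 0.84 in thinned cells, 1.02 with size factors, -0.16 with the mixed cluster and 0.08 without low-UMI clusters. For round spermatid over spermatocyte (-0.66) it was -0.98 at resolution 2, -0.74 with doublets, -0.52 at 1000 UMIs per cell, -0.40 at 200 per gene, -0.35 by per-cell means, -0.19 with size factors and -0.48 without low-UMI clusters. In the dragon the first step (-0.23) gave -0.19 at 1000 UMIs per cell, -0.39 at 10 per gene, 0.05 at 200, -0.11 by per-cell means, 0.23 thinned and 0.21 with size factors. The second (-0.77) gave -0.83 at resolution 0.5, -0.66 at 200 UMIs per gene, -0.24 thinned and -0.12 with size factors.

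Of the 15 preset lists without the X lists, 1 was beyond the central 95% of random lists in each wallaby step. In the first step this became 2 at resolution 0.5, at 1000 UMIs per cell, with random lists from other genes and with the mixed cluster, and 3 with doublets, 10 UMIs per gene, per-cell means, list members among the variable genes and the minimum over all cells. In the second it became 4 at resolution 2 and at 1000 UMIs per cell, 3 with doublets, per-cell means and without low-UMI clusters, 2 at 10 UMIs per gene, with the minimum over all cells and with random lists from other genes, and 0 at 200 UMIs per gene. In the dragon the 3 lists of the first step became 6 at 1000 UMIs per cell.

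Among genes that differed at least 2-fold, those that changed sign in wallaby spermatocyte over spermatogonium were SMC6 (-0.11, thinned), and NSMCE2 (-0.50) and LEMD2 (-0.09) without low-UMI clusters. At resolution 0.5, with doublets, at 1000 UMIs per cell, with the mixed cluster and without low-UMI clusters, ATRIP was at -0.09, -0.60, -0.33, -0.12 and -0.31, and RPL39 at -0.89, -1.47, -1.19, -0.91 and -1.02. In round spermatid over spermatocyte, PRIM1 (-0.01), GPI (0.03) and ENO1 (0.19) did so at resolution 2 and CENPI (0.20) by per-cell means. In the dragon NSMCE1 (-0.03) did so in the first step in thinned cells. Among lists beyond the central 95%, dragon damage signalling (0.23) in the second step did so in thinned cells. Other lists also turned there, such as damage signalling (0.22), Polycomb (0.55) and histone exchange (0.17) in the first dragon step.

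The dragon difference between the X lists was -1.16 in thinned cells for spermatocyte over spermatogonium and -1.73 for round spermatid over spermatogonium. The wallaby difference had no value at 200 UMIs per gene or in thinned cells, where too few list members were left. Its value of 0.63 became -1.64 at resolution 0.5, -2.35 with doublets, -2.54 at 1000 UMIs per cell and -0.94 at 10 UMIs per gene.

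Shared genes with the same sign in the first step (54.1%) were 58.5% at resolution 0.5, 58.7% with doublets, 58.2% at 1000 UMIs per cell and with the mixed cluster, 55.9% at 10 UMIs per gene, 51.8% by per-cell means, 49.8% thinned, 56.0% with size factors and 56.6% without low-UMI clusters. In the second (68.9%) they were 67.1% at 1000 UMIs per cell, 67.0% at 10 and 66.5% at 200 per gene, 66.2% by per-cell means and without low-UMI clusters, and 61.5% with size factors.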

Other observations

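The X tests below were chosen after the lower summed share had been seen, with their predictions written before each was run. Elongating spermatids, a stage outside the planned comparisons, held lower levels of most measured axoneme RNAs. Axoneme genes were at least 2-fold lower than in round spermatid-like cells in 23 of 26 wallaby cases (median -4.06, percentile 1.65) and 20 of 26 dragon cases (median -3.31, percentile 2.97, inside the central 95% of random lists), against medians over all named genes of -1.63 and -2.18. In the wallaby BRDT was 319-fold lower (233 to 449.8), at 9.47 against 3025 CPM, and DNAH7, a dynein heavy chain, had a log2 ratio of -8.06. YBX2 was 11.2-fold higher (8.92 to 14.3) and FOXJ1, a regulator of cilia, 10.7-fold (7.29 to 16.3). GLRX3, an iron-sulphur protein, was 49.9-fold higher (35.7 to 72.2), with 62.2 CPM in somatic cells. In the dragon ALDOA was 22.1-fold higher (19.5 to 25.2) and LDHB 17.6-fold (16.3 to 19.1). AMMECR1 was 1271-fold lower (352 to 10500). Size factors moved the median feature of this step by 2.24 in the wallaby and 1.82 in the dragon.

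AKAP4, a protein of the sperm tail sheath that the wallaby reference places on X, held 78.3% of the X UMIs of wallaby elongating spermatid-like cells, at 7273 CPM against 420 in round spermatid-like and 160.4 in somatic cells. IL2RG held 9.7%. Without AKAP4 the X genes held 201.9 UMIs per 100000, and without both 112. AKAP4 and IL2RG were singled out after their values were seen. In somatic cells HMGB4, another spermatid gene, stood at 131 CPM.

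Meiotic silencing of the X may account for the lower summed share of long-arm genes in wallaby spermatocyte-like cells, and 3 technical explanations were tested against it. RNA of peritubular or stromal-like cells in the spermatogonium-like class would bring at most 3.49% of the difference of 163 UMIs per 100000, from a share of 0.838% (upper bound 1.36%). RNA of Sertoli-like and Leydig-like cells, which held 592 and 1042 long-arm UMIs per 100000, was not measured there. Without TAF1, THOC2 and MTMR1, the 3 most abundant members, the ratio was 0.313 (0.273 to 0.359), and without the 4 ribosomal proteins 0.274 (0.244 to 0.308). Each stayed below the short-arm ratio of 0.536 (0.503 to 0.570). Ribosomal protein RNA as a whole was higher in spermatocyte-like (1.48%) than in spermatogonium-like cells (0.377%). Leaving those members out would tend to lower the ratio, so that test shows only that they did not pull it down. In the dragon, where the genes of both lists are held to be autosomal, the long-arm ratio of 0.750 was also below the short-arm ratio of 1.19. The quotients of the 2 ratios were 0.576 in the wallaby and 0.629 in the dragon for spermatocyte over spermatogonium. For round spermatid over spermatogonium they were 0.494 and 0.498, so by these summed shares of all members the X did not stand apart. Leaving out ribosomal proteins, the long-arm ratios of that step were 0.302 in the wallaby and 0.682 in the dragon. Short-arm ratios were 0.628 and 1.15. Without ribosomal proteins the spermatocyte quotients were 0.511 and 0.692, and against somatic cells 0.267 and 0.726, where the wallaby gap was wider. With no UMI added, 41 of 71 wallaby long-arm and 19 of 52 short-arm genes were at least 2-fold lower in spermatocyte-like cells. Dragon counts were 30 of 89 and 14 of 50, so by these counts the wallaby long-arm list stood apart in this step. Only 27 of the 41 and 17 of the 19 wallaby genes had over 3 UMIs in spermatogonium-like cells. All 30 and 14 dragon genes did. Among list genes above that minimum the counts were 27 of 31 and 17 of 32. In the dragon they were 30 of 88 and 14 of 50. In the small wallaby class that minimum favours genes high in it, so how far the list stood apart is not settled. For round spermatid over spermatogonium the counts without that minimum were 40 of 71 and 25 of 52. The dragon held 50 of 89 and 26 of 50, with less of a gap. With 1 UMI added, the long-arm and short-arm medians over those genes for spermatocyte over spermatogonium were -2.28 and -0.83 in the wallaby. In the dragon they were -0.33 and -0.22. The added UMI lowers ratios over the small wallaby spermatogonium-like class, where 17 long-arm and 9 short-arm genes had no UMI. The wallaby short-arm list is itself lower, and the planned difference of list medians (0.63) rests on 5 long-arm genes. The spermatogonium-like class has 33 cells and also scored for spermatocyte markers, so silencing stays a hypothesis that these values do not decide.

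Ribosomal protein RNA varied among clusters of 1 class, from 0.257 to 4.82% of UMIs in the wallaby spermatocyte-like clusters and from 3.33 to 16.0% in the dragon spermatogonium-like clusters. The wallaby spermatogonium-like class held 0.377%, against 1.48% in the spermatocyte-like class and 4.32% in the mixed cluster 10. Wallaby ratios over spermatogonia thus also compare cells that differ in ribosomal protein RNA. The unnamed wallaby cluster 10 held 418 long-arm UMIs per 100000 (393 to 444), more than the spermatogonium-like class.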
